A study of Python bivittatus with 8 samples.

How the data were processed

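Poly-A RNA from the left ventricle of Burmese pythons (Python bivittatus) was sequenced as 8 libraries in 4 groups of 2. The groups were snakes fasted for 28 days and snakes taken 1, 4 or 6 days after a rodent meal of 25% of their body mass, called 1DPF, 4DPF and 6DPF (days post-fed). The authors deposited raw read counts per gene for all 8 libraries in a single table, with a gene length in bases, per the file headers. Per the submitters' processing notes, Trimmomatic 0.36, HISAT2 2.1.0, SAMtools 1.8, featureCounts and DESeq2 1.36.0 were among the tools used. Their settings, the genome build, the annotation, the strand setting and the handling of reads that map to several genes are not given in the sources used here. Counts of overlapping genes, antisense genes and near-identical copies are therefore uncertain.

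The table names genes by numeric identifiers and does not pair them with gene names. No identifier was given a name here. The 47 gene lists and 5 single genes, FOXO1, FOXO3, FOXO4, FBXO32 and TRIM63, that were fixed before the data were examined could not be matched to identifiers. They were not analysed here, and the planned list tests were not run. Gene groups are described instead by the comparison in which they were called, by abundance and by length.

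Each count column was matched to its sample through the sample's description label. Totals ranged from 33203808 to 42250755 counts per library, so 1 read corresponds to between 0.0237 and 0.0301 CPM. Of 21368 genes, 16986 passed edgeR's filterByExpr (minimum count 10, minimum total 15) and were tested. These genes held at least 99.978% of the reads of each library, and 1547 of the remaining 4382 genes had no read in any library. Counts were scaled with TMM factors, which lay between 0.9623 and 1.066. All 8 libraries entered 1 quasi-likelihood fit (edgeR 4.0.16, glmQLFit and glmQLFTest, R 4.3.3) with group as the sole term. The fit left 4 residual degrees of freedom, with an estimated 3.79 prior degrees of freedom and a biological coefficient of variation of 21.9%. Adjusted p is the Benjamini-Hochberg value over all tested genes, two-sided, and a gene was called when it was under 0.05. Standard errors of log2 fold changes were taken from the fold change and the F statistic. Log2 CPM values used a prior count of 2, so differences of low genes are understated. Nothing in the labels says that the libraries of a group came from separate snakes, so the p-values measure the spread between these libraries, which may be in part technical. The labels' protocol gives n = 6 for the snakes used in sequencing and proteomics, fewer than the 8 libraries, and does not say how they were divided. The SDs and n of 2 given per group therefore count libraries.

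Within each group the 2 libraries differed by more than sampling noise (chi-square per degree of freedom between 48.6 and 68.7), so none was treated as a library deposited in duplicate. This does not show that they are separate snakes, and they were counted as replicates because the labels number them so. The labels number the replicates of every group 1 and 2 and do not say that a number links the groups, so the fit has no term for it. The description labels of the replicate 1 libraries are consecutive over the 4 groups, and those of replicate 2 follow them. What their order stands for is not given, so a batch tied to the replicate number stays possible.

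The edgeR steps were tested on counts simulated from the real means, dispersions and library sizes with 200 genes changed. For 1DPF against fasted, with 16795 simulated genes tested, 25.4% of genes changed by 2-fold and 69.7% of those changed by 4-fold were recovered. None of the 67 genes changed by 1.5-fold was recovered, and 8 of the 71 calls were false. The data had 3268 calls in this comparison, and the Benjamini-Hochberg threshold is less strict when more genes change. These shares therefore do not give the recovery in the real comparison. For 6DPF against 4DPF, with 16795 simulated genes tested, the recovered shares were 2.99%, 16.4% and 75.8% at 1.5-fold, 2-fold and 4-fold, and 5 of the 68 calls were false. Comparisons that share a group share its libraries. Overlaps were therefore set beside the count that independent lists give. Covariances and correlations of log2 changes were set beside those in 20 simulated data sets with no change between groups. Such data give almost no calls, so they hold no value for an overlap of calls.

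Alternatives fixed before the data were examined were DESeq2 1.42.0, limma 3.58.1 with voom, RLE factors, no filter on low counts, a mean of at least 1 CPM, the replicate number as a block, a fit on the 2 compared groups alone, and each library left out in turn. A surrogate variable (sva 3.50.0) and the removal of each library's trend with gene length (loess, span 0.5, degree 1) were added after the data were seen. The preset rule for named genes took, in every comparison, the called genes with a symbol, a mean log2 CPM of at least 3 and both libraries of a group above both of the other, ranked by log2 change, together with members of the preset lists and the 5 single genes. As no symbol was at hand, the rule could be used neither in full nor with its condition on symbols. Its ranking was kept for 1DPF against fasted alone, a restriction chosen after the data were seen, and met by 1308 higher and 1273 lower genes. The 2 of these with the largest increase and the 2 with the largest decrease are given by identifier and followed through all groups.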

Results

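The series asked which transcripts accompany the shrinking of the python heart after the growth that follows a meal. Per the design text, 1DPF stands for active growth, 4DPF for early regression and 6DPF for later regression. Gene expression was measured in 8 left ventricle libraries, with 2 each from fasted, 1DPF, 4DPF and 6DPF snakes. Library totals were 33203808 and 36500222 counts for the fasted group, 36972977 and 40643771 at 1DPF, 40500773 and 38013128 at 4DPF, and 42250755 and 38942637 at 6DPF. Between 18349 and 18675 genes had at least 1 read in a library. The most abundant gene took between 1.77% and 2.84% of a library's reads, and the 10 most abundant took between 11% and 13.6%. Genes are known here by number alone, so the groups below are defined by when their expression changed.

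The 1DPF libraries stood apart from all the others on the first principal component. This component held 36.4% of the variance and put the 1DPF libraries at 63 and 68.3, while the other 6 libraries lay between -45 and 1.61. The second component, with 24.1%, placed the fasted libraries at 44.9 and 52.2, above the remaining 6, which lay between -47.1 and 17. Libraries of the same group differed by a root mean square of 0.49 to 0.65 in log2 CPM over the tested genes, and libraries of different groups by 0.58 to 0.97. The ranges overlap because 4DPF and 6DPF libraries of the same replicate number were close, at 0.58 for replicate 1 and 0.60 for replicate 2. After the replicate spread was subtracted, the root mean square log2 change per gene was 0.63 for 1DPF against fasted, 0.54 for 4DPF against fasted and 0.43 for 6DPF against fasted. Against 1DPF it was 0.54 for 4DPF, as large as that of 4DPF against fasted, and 0.74 for 6DPF. It was 0.27 between 4DPF and 6DPF. The spread subtracted was pooled over the 4 groups and took the groups as independent. The 0.27 may therefore be too low if the replicate numbers link 4DPF and 6DPF.

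**Figure D1:**
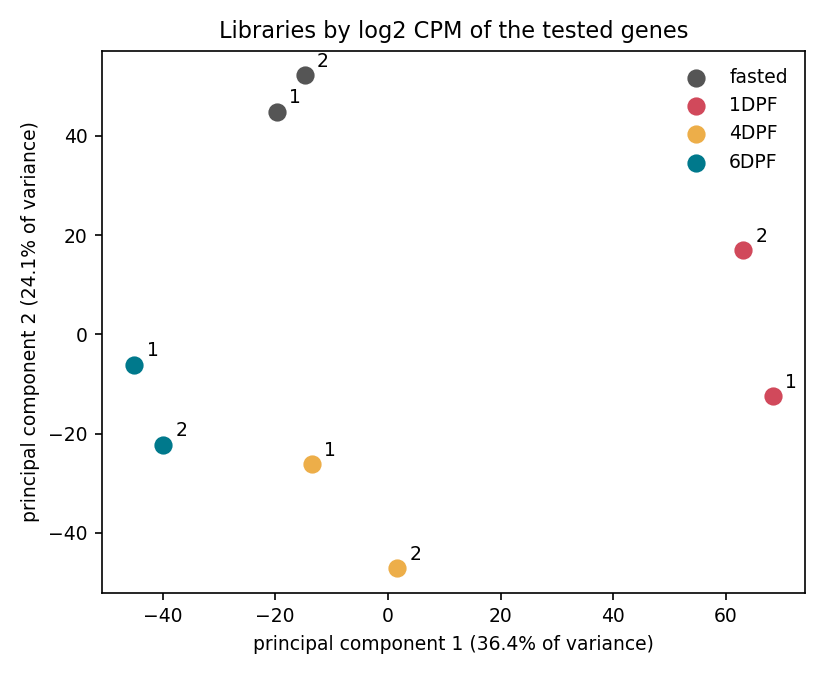
First and second principal components (axes, with the share of variance of each) of log2 CPM over the tested genes. Each point is 1 library, coloured by group and numbered by replicate; the 1DPF libraries lie at 63 and 68.3 on the first component and the other 6 libraries lie at or below 1.61.

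Fasted and 1DPF ventricles were compared to ask what changes as the heart grows. Of 16986 genes tested, 3268 (19.2%) changed, in nearly equal numbers: 1627 were higher and 1641 lower at 1DPF. The median log2 change was 0.88 among the higher genes and -0.95 among the lower ones. At least a 2-fold change was seen in 662 higher and 759 lower genes, and at least a 4-fold change in 155 and 169. The higher genes held 7.21% of the counts in fasted ventricle and 15.4% at 1DPF, and the lower genes went from 16.1% to 8.48%. These shares were taken from the libraries in which the genes were called, so they overstate the shift. With the genes in 4 bins of equal size by abundance, 27.1% of the most abundant bin (median 78.4 CPM) were called, against 6.48% of the least abundant (median 0.919 CPM). A change is harder to call at low counts, so these shares do not show that abundant genes responded more often. Among the 50 most abundant genes, 3 rose and 7 fell. Genes lower at 1DPF had a median length of 3269 bases and those higher 2583, against 2503 over all tested genes. The number of genes called was 1218 without fasted replicate 1, 716 without fasted replicate 2, 1946 without 1DPF replicate 1 and 1604 without 1DPF replicate 2.

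Gene 103062969 showed the largest increase at 1DPF among called genes with a mean log2 CPM of at least 3. It rose from 90.7 CPM ± 25.8 (SD, n = 2) in fasted ventricle to 1378 ± 320 (SD, n = 2), a log2 change of 3.93 (SE 0.29; edgeR quasi-likelihood adjusted p = 0.000894). The next, gene 103058276, went from 5.84 ± 1.19 to 76.2 ± 79.5 CPM (SD, n = 2 each), with 132 CPM in 1 of the 1DPF libraries and 19.98 in the other. Its log2 change of 3.70 (SE 1.02, edgeR adjusted p = 0.0413) became 1.77 without 1DPF replicate 1 (adjusted p = 0.204). Without fasted replicate 1 or 2 the log2 change was about as large, at 3.54 and 3.96, but was not called (edgeR adjusted p = 0.192 and 0.183), and over the alternatives run for single genes (DESeq2, RLE factors, the replicate number and each library left out) its adjusted p ran from 0.00841 to 0.204. Gene 103048176 had the largest decrease among such genes, from 76.0 ± 21.3 CPM to 0.883 ± 0.390 (SD, n = 2 each), a log2 change of -6.42 (SE 0.41, edgeR adjusted p = 0.000592). Gene 103067417 fell from 125 ± 10.5 to 3.35 ± 2.87 CPM (SD, n = 2 each), a log2 change of -5.23 (SE 0.57, edgeR adjusted p = 0.00191). These genes are 2876, 1071, 3332 and 2633 bases long in the deposited table.

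**Figure D2:**
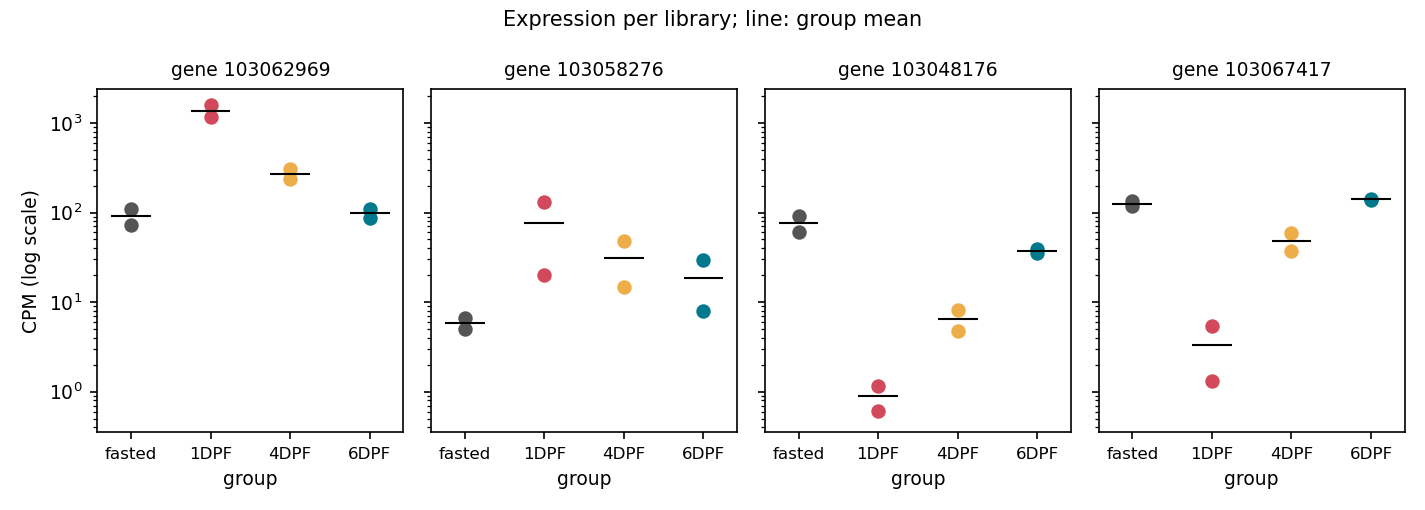
CPM on a log axis for the 2 genes with the largest increase and the 2 with the largest decrease at 1DPF among called genes with a mean log2 CPM of at least 3, by group; points are libraries and lines group means of 2 libraries. Gene 103062969 peaks at 1378 CPM and is at 98.2 CPM at 6DPF, and gene 103067417 drops to 3.35 CPM and is at 140 CPM at 6DPF.

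The step from 1DPF to 4DPF covers the onset of regression. Here 1046 genes changed, 673 higher and 373 lower at 4DPF, so that 64.3% of the called genes rose. The median log2 change was 1.10 among the higher and -0.81 among the lower genes, with 143 genes rising and 21 falling at least 4-fold. Of the 673 genes that rose, 332 had been called lower at 1DPF than fasted and 5 higher. Of the 373 that fell, 267 had been called higher at 1DPF and 3 lower. Independent lists would share 65 and 35.7 genes in those opposite directions. The covariance of the log2 changes across genes was -0.28, against -0.079 in 20 simulated data sets without change. Their correlation was -0.55, close to the -0.5 of the simulated data. Both comparisons use the 1DPF libraries, and part of the excess may come from them. Gene 103062969 fell by 2.35 on the log2 scale to 271 CPM ± 48.7 (SD, n = 2; edgeR adjusted p = 0.0127). Genes 103048176 and 103067417 rose by 2.86 and 3.85 (edgeR adjusted p = 0.0151 and 0.0173), to 6.45 ± 2.37 and 48.3 ± 15.1 CPM (SD, n = 2 each). Gene 103058276 stood at 31.5 ± 23.5 CPM (SD, n = 2) and did not pass the test. Calls for this step numbered 15 without 1DPF replicate 2, 72 without 4DPF replicate 1, 302 without 1DPF replicate 1, 337 without 4DPF replicate 2, and 343 and 345 without fasted replicates 1 and 2, while DESeq2 called 2205 and edgeR on these 2 groups alone called 0 (3758 genes at an unadjusted p under 0.05; limma voom on all libraries called 848). With 1 library left out, the share of higher genes among the calls ran from 46.7% (7 higher and 8 lower, without 1DPF replicate 2) to 91.7% (66 higher and 6 lower, without 4DPF replicate 1). Without 1DPF replicate 2, genes 103062969 and 103048176 had log2 changes of -2.08 and 2.47 and missed the threshold (edgeR adjusted p = 0.0516 and 0.0756, the highest over the alternatives run for single genes, with DESeq2 the lowest at 1.62e-16 and 1.76e-12).

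Between 4DPF and 6DPF, early and later regression, 15 genes changed, 9 higher and 6 lower at 6DPF. All 15 had fitted changes of at least 2-fold. Smaller changes could rarely be called, as 2.99% of the 1.5-fold changes were recovered in the simulated counts for this comparison. The 9 that rose had a median of 41.7 CPM in fasted ventricle, 11.1 at 1DPF, 20.2 at 4DPF and 60.5 at 6DPF, and 6 of them had been called lower at 1DPF than fasted (0.869 for independent lists). The 6 that fell had medians of 54.1, 286, 165 and 49.5 CPM in the same order, and 5 of them had been called higher at 1DPF (0.575 for independent lists). Of the genes followed by number, none passed the edgeR test for this step. Gene 103048176 had a log2 change of 2.53 (SE 0.33, edgeR adjusted p = 0.0607) and gene 103062969 one of -1.46 (SE 0.27, edgeR adjusted p = 0.10). DESeq2 called both (DESeq2 adjusted p = 6.59e-12 and 5.87e-06). Without adjustment 2687 genes had p under 0.05. DESeq2 called 731 genes, including the 15, limma voom called 18, and edgeR on these 2 groups alone called 0 (2241 genes at an unadjusted p under 0.05). Without either fasted library edgeR called 1 gene, which was not among the 15, without either 4DPF library it called 1 of the 15, and without either 6DPF library it called 0, with 2124 and 2429 genes at an unadjusted p under 0.05.

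**Figure D3:**
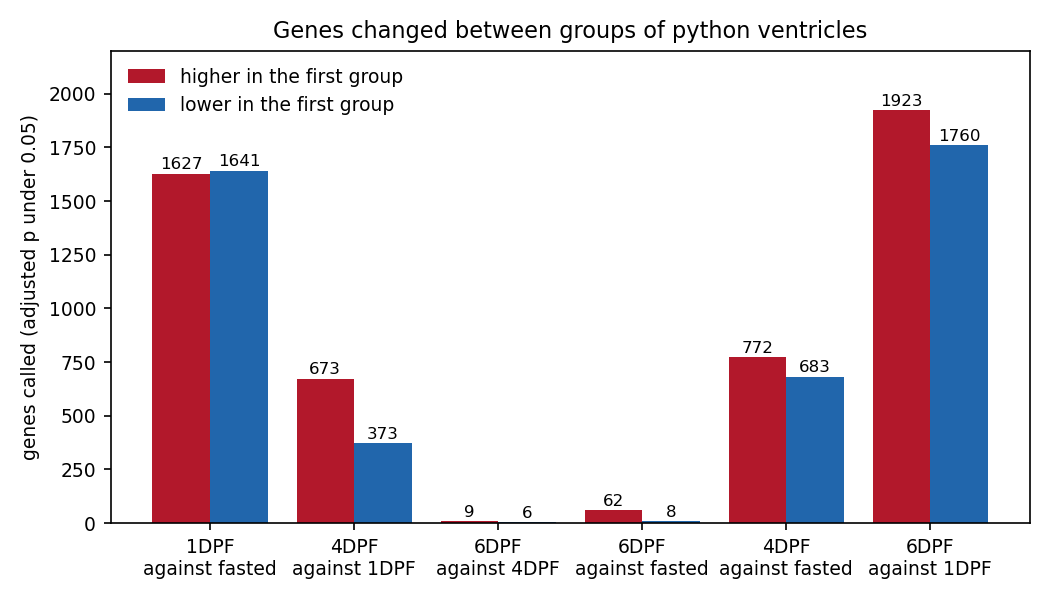
Number of genes called (vertical axis, edgeR adjusted p under 0.05) as higher (red) or lower (blue) in the first-named group of each of the 6 comparisons, which are listed along the horizontal axis. The counts run from 9 and 6 for 6DPF against 4DPF to 1923 and 1760 for 6DPF against 1DPF.

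Fed hearts at 4DPF and 6DPF were next compared with fasted ones. At 4DPF, 1455 genes differed from fasted, 772 higher and 683 lower, with median log2 changes of 1.00 and -0.85. Of the 1627 genes higher at 1DPF than fasted, 380 were called higher at 4DPF, and of the 1641 lower at 1DPF, 483 were called lower and 8 higher. Independent lists would share 73.9 higher and 66 lower genes. The covariance of the log2 changes was 0.29, against 0.081 in the simulated data. Their correlation was 0.56, close to the 0.51 of the simulated data. Both comparisons use the fasted libraries, and part of the excess may come from them. The 1455 calls became 3 and 4 without fasted replicates 1 and 2, 29 without 4DPF replicate 1, 381 without 4DPF replicate 2 and 2646 with DESeq2.

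At 6DPF, 70 genes differed from fasted, of which 62 (88.6%) were higher and 8 lower. The 62 had a median log2 change of 2.83, and 41 of them rose at least 4-fold. With few genes called, the threshold favours large fitted changes, so these sizes are in part set by the test. Their median expression was 2.37 CPM in fasted ventricle, 2.85 at 1DPF, 10.5 at 4DPF and 16.7 at 6DPF, and in 16 of them both fasted libraries were under 1 CPM. At 4DPF, 51 of the 62 were called higher than fasted, against 2.82 for independent lists. The covariance of the log2 changes over all tested genes was 0.29 and the correlation 0.71, against 0.081 and 0.51 in the simulated data. Part of that excess may come from the shared fasted libraries. At 1DPF 12 of the 62 were called higher than fasted and 5 lower. In the comparison of 4DPF with 1DPF, which uses none of the same libraries, 39 of the 62 were called higher and 3 lower, against 2.46 higher in both for independent lists, which leaves out that both tests use dispersions from the same fit. The 39 became 19 and 1 without 1DPF replicates 1 and 2, 15 without 4DPF replicate 1 and 0 in edgeR on 1DPF and 4DPF alone (3758 genes at an unadjusted p under 0.05 in all; DESeq2 called 46 of the 62), with 56 of the 62 log2 changes positive in each of these fits. The 8 lower genes were all called lower at 4DPF as well, with a median log2 change of -1.39 at 4DPF and -1.11 at 6DPF. The 70 calls became 0 without either fasted or either 6DPF library (edgeR, with between 1452 and 2707 genes at an unadjusted p under 0.05), 46 and 41 without 1DPF replicates 1 and 2, and 118 without 4DPF replicate 2. Limma voom called 0 (2746 genes at an unadjusted p under 0.05), DESeq2 called 788, with a smaller share of higher genes (504 higher and 284 lower, or 64%), and a fit with 1 surrogate variable called 351 (256 higher and 95 lower, or 72.9%).

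Of the genes followed by number, none was called between 6DPF and fasted. Genes 103062969 and 103067417 were at 98.2 ± 16.3 and 140 ± 1.91 CPM at 6DPF (SD, n = 2 each), with log2 differences from fasted of 0.12 (SE 0.26) and 0.16 (SE 0.47). Gene 103048176 was at 37.1 ± 2.54 CPM (SD, n = 2), with a log2 difference of -1.04 (SE 0.31, edgeR adjusted p = 0.166), and gene 103058276 was at 18.6 ± 15.0 CPM (SD, n = 2), with one of 1.67. DESeq2 called gene 103048176 lower (adjusted p = 0.0279).

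**Figure D4:**
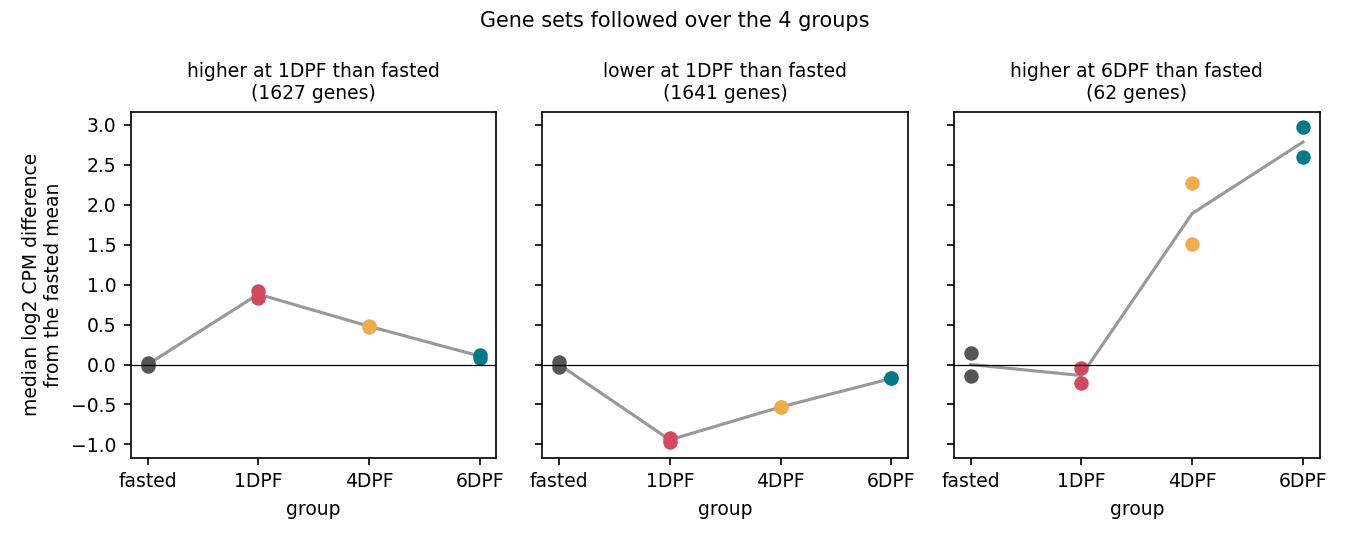
Median over each gene set of log2 CPM minus the mean of the fasted libraries (vertical axis), by group; points are libraries and the line joins the means of 2 libraries. Each set was chosen with the fasted libraries, which exaggerates its distance from 0; the genes higher at 6DPF than fasted have medians of 1.51 and 2.27 at 4DPF and 2.60 and 2.97 at 6DPF.

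Between the growth and later regression times, 1DPF and 6DPF, 1923 genes were higher and 1760 lower at 6DPF. Most genes that changed at 1DPF were called again here, in the opposite direction. Of the 1627 genes higher at 1DPF than fasted, 1143 were called lower at 6DPF than 1DPF and 3 higher. Of the 1641 lower at 1DPF, 1081 were called higher at 6DPF and 1 lower. Independent lists would give 169 and 186 genes in these opposite directions. Across genes, the covariance of the 2 sets of log2 changes was -0.47 and the correlation -0.73, against -0.08 and -0.5 in the simulated data. There both arise from the shared 1DPF libraries alone, and part of the excess in calls may come from those libraries. Gene 103062969 fell by 3.81 between 1DPF and 6DPF and genes 103048176 and 103067417 rose by 5.39 and 5.38 (edgeR adjusted p = 0.0011, 0.00101 and 0.00191). The comparison called 2385 and 1838 genes without 1DPF replicates 1 and 2, 2155 and 1923 without 6DPF replicates 1 and 2, and 2193 in a fit of these 2 groups alone. The 1143 genes became 484 and 292 without fasted replicates 1 and 2, 549 without 1DPF replicate 2 and 629 without 6DPF replicate 1, and the 1081 became 485 and 365 without the fasted replicates, 621 and 504 without the 1DPF replicates and 617 without 6DPF replicate 2.

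Across the whole course, 3625 genes (21.3%) differed among the 4 groups. Expression was highest at 1DPF in 38% of these genes and lowest at 1DPF in 42%, against 32.1% and 31.8% of all tested genes. By group mean, the commonest courses were a peak at 1DPF with the minimum at 6DPF (691 genes), a minimum at 1DPF with the peak at 6DPF (667), a minimum at 1DPF with the peak in fasted ventricle (649) and a peak at 1DPF with the minimum in fasted ventricle (601). Which group is the extreme was read from means of 2 libraries and not tested. As 70 genes were called between 6DPF and fasted, most of these courses do not separate 6DPF from fasted. A peak at 4DPF was seen in 497 genes and a minimum there in 388. The total was 1590 and 1279 without fasted replicates 1 and 2, 2025 and 1598 without 1DPF replicates 1 and 2, and 5442 with DESeq2's likelihood ratio test.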

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

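The surrogate variable and the removal of the length trend were chosen after seeing the data. No gene called by edgeR with all libraries was called in the opposite direction under any alternative. RLE factors, a mean of at least 1 CPM and removal of the length trend kept every count of changed genes within 1.5 times its main value. The 2 counts of genes with opposite courses were not run with limma voom, with a mean of at least 1 CPM or on 2 groups. In the order 4DPF against 1DPF, 6DPF against 4DPF, 6DPF against fasted, 4DPF against fasted and across the 4 groups, DESeq2 called 2205, 731, 788, 2646 and 5442 genes, where edgeR called 1046, 15, 70, 1455 and 3625. With the surrogate variable the first 3 of these were 2015, 211 and 351. Without a filter, 33 genes were called for 6DPF against 4DPF and 135 for 6DPF against fasted. Limma voom called 0 for 6DPF against fasted, with 2746 genes at an unadjusted p under 0.05. Fits on the 2 compared groups alone, which leave 2 residual degrees of freedom, called 0 genes for 4DPF against 1DPF and 0 for 6DPF against 4DPF in edgeR (3758 and 2241 at an unadjusted p under 0.05), 191 for 6DPF against fasted and 2193 for 6DPF against 1DPF. The cause of these differences was not tested. With the replicate number as a block (replicate block), 670 genes were called for 4DPF against 1DPF and 0 for 6DPF against 4DPF (2659 at an unadjusted p under 0.05), the other counts stayed within 1.5 times, and gene 103058276 was no longer called at 1DPF against fasted (adjusted p = 0.0647), with a log2 change of 3.90 against 3.70 without the block. The replicate differences of 4DPF and 6DPF correlated across genes at 0.43. Those of 1DPF correlated with 4DPF at -0.34 and with 6DPF at -0.20, and the other 3 pairs of groups lay between -0.11 and 0.086. It was therefore not established that the numbers pair the samples, although the description labels of each replicate number are consecutive. With 1 library left out, the lone library of its group is assumed to vary as the other groups do. Counts then ranged from 716 to 3042 for 1DPF against fasted, 15 to 812 for 4DPF against 1DPF, 0 to 11 for 6DPF against 4DPF, 0 to 118 for 6DPF against fasted, 3 to 1258 for 4DPF against fasted, 1838 to 3385 for 6DPF against 1DPF and 1279 to 2761 across the 4 groups. Genes higher at 1DPF than fasted and lower at 6DPF than 1DPF numbered 292 to 1078, and those with the opposite course 365 to 932. DESeq2 called 3 further changes of the genes followed by number: 103062969 and 103048176 for 6DPF against 4DPF and 103048176 for 6DPF against fasted. The tests of preset gene lists were not run, as the identifiers have no names here. Whether depth or the number of libraries limits the precision was not tested.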

Other observations

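The test of the 62 genes in pairs of 4DPF and 1DPF libraries, that of their direction between the 4DPF libraries, the removal of the length trend as an alternative, and the decision that thinning cannot judge depth were chosen after the data were seen.

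Genes in the middle of the abundance range were also among those called after feeding. At 1DPF, 19.2% of the genes in the abundance bin with a median of 7.36 CPM and 24.2% in the bin with a median of 23.7 CPM were called against fasted. These shares, too, depend on how precisely genes of each abundance were measured. At 4DPF, genes lower than fasted had a median length of 3879 bases and those higher 2324. At 6DPF the medians were 6011 bases for the 8 lower genes and 2196 for the 62 higher ones. After each library's trend with gene length was removed, 4DPF against fasted had 621 higher and 664 lower genes, in place of 772 and 683. Whether such a trend produced the length differences at 1DPF, 4DPF or 6DPF was not tested. Among the 50 most abundant genes, 2 rose and 4 fell at 4DPF against fasted, and 4 rose and 4 fell at 6DPF against 1DPF.

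The return of the 1DPF response may go on between 4DPF and 6DPF, although 15 genes were called for that step. The 1DPF minus fasted and the 6DPF minus 4DPF changes share no library. Across genes, which are not independent replicates, they correlated at -0.49, against -0.0045 in simulated data without change. Each of the 16 choices of 1 library per group gave a negative value, between -0.47 and -0.15. Of the genes higher at 1DPF than fasted, 1496 of 1627 had a negative log2 change from 4DPF to 6DPF (median -0.36), and of the lower ones 1478 of 1641 had a positive one (median 0.34).

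The excess of higher over lower genes at 6DPF against fasted, 62 against 8 (88.6% higher) in edgeR and 504 against 284 (64% higher) in DESeq2, was weighed against 3 explanations. A trend with gene length that differs between libraries cannot be the whole cause, since 87.9% of the 66 genes called after its removal were higher. Calls with 1 library left out were too few to decide on a single library. The 4DPF and 1DPF libraries did not enter the contrast of 6DPF with fasted. In each of the 4 pairs of a 4DPF and a 1DPF library, at least 83.9% of the 62 genes were higher at 4DPF. The share of all tested genes was at most 49.4%. This argues against a single library as the source of the rise of the 62 genes. It does not address why few lower genes were called, as 7 of those 8 had a negative log2 change from 1DPF to 4DPF. A single library behind the excess itself therefore stays open. The share of another cell type may have risen: 80.6% of the 62 genes were higher in 4DPF replicate 1 than in replicate 2, against 50.4% of all tested genes, and replicate 1 was the higher for 44 of the 62 in the fasted group, 49 at 1DPF and 51 at 6DPF, but shared regulation within a cell type predicts this too. The 2 cannot be told apart here, because no marker gene could be matched to an identifier, and the time after the meal stays open as the biological explanation. A preparation that differed between libraries numbered 1 and 2 could also put replicate 1 higher in every group, and was not tested.

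Replicate differences of some groups were correlated. The difference between replicates 1 and 2 correlated across genes at 0.43 between 4DPF and 6DPF, at -0.34 between 1DPF and 4DPF and at -0.20 between 1DPF and 6DPF, although these groups share no library. A trend with gene length is argued against, as the 4DPF and 6DPF correlation was 0.428 after its removal. Sequencing depth stays open: in 5 thinnings to 33203808 counts the correlation was at least 0.422, but the replicates' totals differed by 6.54% at 4DPF and 8.49% at 6DPF, so thinning changed too little to decide. Differences between animals, in tissue sampled or in preparation could produce such correlations and stay open. A preparation shared by all libraries of the same number, acting alone and alike in every group, would give no negative ones. It could still act beside another cause, so it is not excluded. No biological explanation was tested.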
